A study of Rattus norvegicus with 21 samples.

How the data were processed

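The values used were log2 signals as deposited by the authors, made per the submitters' processing notes by robust multi-array averaging (RMA) of the scanned arrays, with a version not given in the sources used here. Each array took 100 ng of total RNA, amplified and labelled with biotin. The table held 31099 probe sets on 21 arrays, of which 20832 were paired with exactly 1 gene, 436 with several and 9831 with none in the probe table used here. Probe sets with several genes or none were not named. The 14218 genes left were each represented by the probe set with the highest mean over all arrays, and 4526 of them had 2 or more probe sets. No further scaling was applied.

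Groups, comparisons, tests, gene lists and the alternatives listed beside them were fixed before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3, in a model with 1 mean per group over all 21 arrays and 15 residual degrees of freedom, with moderated t-tests and Benjamini-Hochberg adjustment over all genes of a comparison at 0.05. Each dose was compared with the 6 vehicle arrays, 978.5 mg/kg was compared with 489.2 mg/kg, and a trend was fitted on dose rank from 0 to 5. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. The labels give 3 arrays per dose, which limits the precision of every estimate.

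The 32 gene lists were written from general knowledge, with 553 of 648 entries matched, and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. Within a list, members were also adjusted over the list alone. List means per array were compared by exact permutation of the 9 arrays of a comparison. A clock axis was taken as the mean of Dbp, Per3 and other late-day genes minus that of Npas2, Nfil3 and other late-night genes, each relative to the vehicle mean.

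Benchmark doses were estimated for genes with a trend and at least a 1.5-fold change at 1 or more doses. A monotone curve was fitted to the group means by isotonic regression, and the dose at which it left the vehicle level by 1 residual SD was found by linear interpolation, with 95% intervals from 500 resamplings of residuals. Overlaps between doses were compared with the number expected of independent lists, with 100 simulated sets of unchanged groups that share a vehicle, and with 20 ways of giving 3 separate vehicle arrays to each dose.

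Genes were named by a fixed rule. At 978.5 mg/kg it took the 12 largest rises and 12 largest falls among called genes in which all treated arrays lay beyond all vehicle arrays, and at the other doses the 5 largest of each. It added the 10 trend genes with the smallest p, 4 members of each list, the 5 largest rises and falls between the highest doses, and a set of known genes chosen in advance. Placeholder symbols were left out. Cyp2b1 and G6pc belong to that set but have no probe set of their own, so they are not named here. Some genes of the rule were left out for length.

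The pipeline was checked on simulated data, with 100 of 14218 genes changed at each size. Noise was drawn independently for each gene and array at the gene's residual SD, so correlation between genes and structure among arrays were absent. The false calls and the check of camera below therefore do not show how these tests behave with correlated genes. At 1.5-fold the share of changed genes recovered was 85% at 61.2 mg/kg, 83% at 122.5 mg/kg, 87% at 244.6 mg/kg, 83% at 489.2 mg/kg and 78% at 978.5 mg/kg. At 2-fold it was 96%, 96%, 97%, 98% and 98% in the same order, with 13, 9, 8, 8 and 9 false calls. For 978.5 against 489.2 mg/kg 73% and 97% were recovered with 13 false calls, and for the trend 89% and 96% with 7. In camera at 978.5 mg/kg a shift of 0.5 put into 1 list was found (limma camera adjusted p = 1.46e-41) and 0 of the lists sharing no gene with it were called. Benchmark doses of steep simulated lines, set at 30.6 mg/kg, were recovered at a median of 29.6 mg/kg, while shallow lines set at 244.6 mg/kg gave 183.6 mg/kg, so values high in the dose range may be too low.

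Alternatives covered the mean of a gene's probe sets, every probe set tested, genes above the median level, eBayes with trend and robust options, array weights, median centring, a second quantile normalisation, a floor at the 20th percentile, fold thresholds with adjusted and unadjusted p, the replicate number as a block, each array left out, and only the arrays compared. For the trend they covered dose in mg/kg, treated arrays alone and an F test, and for benchmark doses 0.5 and 1.5 residual SD and a power model. After the first results were seen, the clock axis, fits without arrays in doubt, fits with that axis as a covariate, alternatives for the genes shared between doses and the contrast of 244.6 with 489.2 mg/kg were added.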

Results

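Liver RNA of 21 male Harlan Sprague Dawley rats was measured on rat gene expression arrays after short oral dosing with 2-ethylhexyl diphenyl phosphate, an organophosphate ester used as a flame retardant and plasticiser, or with its corn oil vehicle alone. The labels give 6 groups, with 6 vehicle arrays and 3 arrays each at 61.2, 122.5, 244.6, 489.2 and 978.5 mg/kg. The rats were dosed by gavage on 4 days and the left liver lobe was taken on day 5. The protocol speaks of 5 vehicle rats and rounds the doses to whole numbers from 61 to 979 mg/kg, whereas 6 arrays carry the dose 0, and all 6 were used as vehicle. Array medians lay between 6.33 and 6.41 on the log2 scale. The mean correlation of an array with the other arrays ran from 0.988 for vehicle replicate 6 to 0.994. The median SD between arrays of a group was 0.135 for the vehicle and between 0.101 and 0.124 for the treated groups. The vehicle value rests on 6 arrays and the others on 3 each. Such a median runs lower with fewer arrays, so these values do not show a wider spread in the vehicle. The comparisons ask which of 14218 measured genes differed from the vehicle at each dose, and from what dose on. Errors of log2 differences are standard errors from limma with 3 treated and 6 vehicle arrays, adjusted p-values are Benjamini-Hochberg values over all genes, and in each gene said to rise or fall every treated array lay beyond all vehicle arrays unless another number is given.

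At 978.5 mg/kg, the highest dose, the largest rises were those of Akr1b7, Ces2c and Sult2a2, enzymes that act on aldehydes, esters and steroids. Transcripts of Akr1b7, an aldo-keto reductase, rose by 3.87 ± 0.71 on the log2 scale (SE, n = 3 against 6, 14.7-fold, limma adjusted p = 0.00158). Its arrays stood at 9.07, 10.84 and 7.42, so its rank as the largest rise rests on replicate 2. Ces2c, a carboxylesterase, rose 13.8-fold (3.79 ± 0.26, limma adjusted p = 6.13e-08) and Sult2a2, a hydroxysteroid sulfotransferase, at least 13.7-fold (3.78 ± 0.26, limma adjusted p = 6.13e-08), since its vehicle level of 3.69 lay near the lowest signals of the arrays and the fold is a lower bound. The taurine transporter Slc6a6 fell by 3.71 ± 0.27 (13.1-fold, limma adjusted p = 7.46e-08), with its other probe sets at -2.16 or below. Scd, the desaturase that makes monounsaturated fatty acids, fell by 3.00 ± 0.59 (8.02-fold, limma adjusted p = 0.00272). In all, limma called 1457 genes, of which 878 rose and 579 fell, and 102 of them changed at least 2-fold, 66 upward and 36 downward. The count was 702 without replicate 3 of this dose and 904 without replicate 1. With a clock axis, built after results were seen from genes that themselves shifted with dose, as a covariate 116 genes passed, 41 of them higher and 75 lower. Over the 1457 genes the median size of the log2 difference went from 0.43 to 0.49 and its median limma SE from 0.10 to 0.23. The calls ended as the errors grew, while the median size did not shrink. A share of 0.88 of the variance of that axis lay between the dose groups, so differences fitted with it are poorly determined.

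Target genes of CAR and PXR, the nuclear receptors that answer to foreign compounds, stood out among the fixed lists at this dose. Of the 24 measured, 16 rose and the others did not pass, while 20 rose when adjusted over the list alone. Their mean log2 difference was 1.06, and camera placed them above the other genes (limma camera adjusted p = 1.51e-21, and adjusted p = 0.00151 with an estimated correlation). Abcc3, which exports conjugates into blood, rose 11.3-fold (3.50 ± 0.30, limma adjusted p = 3.62e-07). Rises were also measured for the drug efflux pump Abcb1a (2.26 ± 0.18), for Alas1, the first enzyme of haem synthesis (1.95 ± 0.19), for Gadd45b (1.75 ± 0.19) and for Cyp3a23-3a1, a main drug-oxidising cytochrome (1.47 ± 0.12), with limma adjusted p-values of 1.31e-07, 2.68e-06, 7.54e-06 and 1.31e-07. Vehicle replicate 6 lay above the other vehicle arrays in Gadd45b, at 6.74. Of the 28 genes for conjugation and export, 17 rose, and 21 rose and 1 fell when adjusted over the list alone (mean 0.71, limma camera adjusted p = 3.4e-17, and 0.00176 with an estimated correlation). They included the glucuronosyltransferase Ugt2b1 (1.38 ± 0.11) and the glutathione transferase Gsta4 (1.04 ± 0.10).

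Genes that the antioxidant regulator NRF2 controls rose alongside these. Of 24, 15 rose, and 17 rose and 1 fell when adjusted over the list alone (mean 0.69, limma camera adjusted p = 1.37e-16, and 0.00272 with an estimated correlation). Gsta3, another glutathione transferase, rose 7.53-fold (2.91 ± 0.23, limma adjusted p = 1.31e-07), and glutathione reductase, Gsr, rose 2.79-fold (1.48 ± 0.15, limma adjusted p = 4.16e-06). The glutathione synthesis subunit Gclm rose by 1.18 ± 0.14 and the quinone reductase Nqo1 by 1.26 ± 0.25, with limma adjusted p-values of 1.7e-05 and 0.00266. Akr7a3, an aflatoxin aldehyde reductase, rose by 1.47 ± 0.26 (limma adjusted p = 0.00126), although vehicle replicate 4 lay apart from the other vehicle arrays in it, at 11.81. Outside the lists, Pir, an iron-binding nuclear protein, rose by 1.48 ± 0.12 (limma adjusted p = 1.31e-07). Some genes, Ephx1 among them (1.01 ± 0.11, limma adjusted p = 1.18e-05), belong to both the CAR and PXR list and the NRF2 list.

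Among the 7 target genes of the aryl hydrocarbon receptor, Cyp1a1 rose 4.71-fold (2.24 ± 0.31, limma adjusted p = 0.000134) and Nqo1 rose, but Cyp1a2, the other classical cytochrome of the list, fell by 0.48 ± 0.13 (limma adjusted p = 0.025). The fall of Cyp1a2 did not pass in limma without replicate 2 (adjusted p = 0.0914) or replicate 3 (adjusted p = 0.0962) of this dose. When adjusted over the list alone, 2 rose and 2 fell. The list's mean was 0.32 and its median -0.14, so camera's direction was downward (limma camera adjusted p = 0.962). The mean of every array lay above all vehicle arrays here and at 244.6 mg/kg (exact permutation p = 0.0119, the smallest that the 84 splits of 9 arrays can give, and 0.0491 after adjustment over 165 such tests), and vehicle replicate 6, at 0.08, lay above the other vehicle arrays in the list's mean. Those 165 tests include the clock axis, which was built after results were seen and reached the smallest p at most doses. Its tests lower the adjusted value, so its place under 0.05 rests on them and is not taken as a call. Carboxylesterases and related esterases gave 3 rises and 1 fall in 15 genes, and the rise of Ces2c was by far the largest (list mean 0.27, exact permutation p = 0.0119, limma camera adjusted p = 0.0939).

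Genes of cholesterol synthesis were higher at 978.5 mg/kg. Of 20, 12 rose, and 15 rose when adjusted over the list alone. Msmo1 rose by 1.19 ± 0.23 (2 of 3 arrays above all vehicle arrays, limma adjusted p = 0.00226), Sc5d by 0.80 ± 0.12 (limma adjusted p = 0.000281) and the squalene synthase Fdft1 by 0.73 ± 0.14 (limma adjusted p = 0.00273). The list's mean was 0.63 and its median 0.69 (limma camera adjusted p = 6.02e-10, but adjusted p = 0.217 with an estimated correlation and exact permutation p = 0.0595). Fatty acid synthesis moved in both directions, with 4 rises and 2 falls in 23 genes, or 5 and 3 when adjusted over the list alone (mean 0.07, limma camera adjusted p = 0.499). Malic enzyme, Me1, rose by 1.57 ± 0.19 (limma adjusted p = 2.96e-05) beside the fall of Scd, and Fasn, the fatty acid synthase, stood at 0.40 ± 0.31 (limma adjusted p = 0.461).

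Of 36 target genes of PPARA, the receptor behind peroxisome proliferation, 3 rose and 4 fell at this dose, with the same numbers when adjusted over the list alone. The 2 clearest were falls. Angptl4, an inhibitor of lipoprotein lipase, fell 2.96-fold (-1.56 ± 0.20, limma adjusted p = 4.49e-05), and Plin2, a lipid droplet coat protein, fell 2.01-fold (limma adjusted p = 9.37e-05). The classical marker Cyp4a1 did not pass (-0.46 ± 0.26, limma adjusted p = 0.297). The list's mean was -0.04, its median 0.02, and camera's direction upward (limma camera adjusted p = 0.962).

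Of the 24 genes of endoplasmic reticulum and integrated stress, 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone (limma camera adjusted p = 0.272). Psat1, an enzyme of serine synthesis, rose 4.53-fold (2.18 ± 0.29, limma adjusted p = 9.54e-05), the asparagine synthetase Asns 3.61-fold (1.85 ± 0.27, limma adjusted p = 0.000207) and Phgdh, another serine synthesis enzyme, by 1.65 ± 0.31 (limma adjusted p = 0.0019). In the list of p53 targets, Mdm2, which marks p53 for breakdown, rose by 0.81 ± 0.09, while the cell cycle inhibitor Cdkn1a fell by 2.18 ± 0.24, both with a limma adjusted p of 9.88e-06. The probe sets of Cdkn1a spread from -2.18 to -0.52. This list of 15 had 2 rises and 3 falls over all genes and when adjusted over the list alone, with a mean of -0.13, a median of 0.09 and a limma camera adjusted p of 0.962.

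Clock genes changed in opposite directions. Dbp, a transcription factor that peaks late in the rat's resting phase, rose 7.32-fold (2.87 ± 0.45, limma adjusted p = 0.000478) and Per3 rose by 1.54 ± 0.20 (limma adjusted p = 5.21e-05), although its probe sets spread from 0.08 to 1.54 and vehicle replicate 2 lay below the other vehicle arrays, at 4.83. Npas2, a partner of the activator Bmal1, fell by 1.75 ± 0.17 (limma adjusted p = 2.51e-06) and the repressor Nfil3 by 1.28 ± 0.16 (limma adjusted p = 3.15e-05). Of 17 clock genes, 6 rose and 4 fell, or 8 and 4 when adjusted over the list alone (list mean 0.31, exact permutation p = 0.0119, limma camera adjusted p = 0.093). A clock axis, the mean of late-day genes minus that of late-night genes, stood 2.09 above the vehicle. It was built after the shifts of its genes had been seen, so it describes the shift and does not test it.

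Male-biased genes moved in both directions, with 2 rises and 2 falls in 13, the same when adjusted over the list alone (limma camera adjusted p = 0.968). The steroid-oxidising cytochrome Cyp3a18 rose by 1.07 ± 0.12 (limma adjusted p = 1.82e-05), while the male-specific Cyp2c11 fell by 0.47 ± 0.07 (limma adjusted p = 0.00035) and the growth factor Igf1 by 0.33 ± 0.07 (limma adjusted p = 0.00371). Of 11 female-biased genes, 4 rose and 1 fell, or 5 and 1 when adjusted over the list alone. The sulfotransferase Sult2a6 rose by 1.98 ± 0.23 (limma adjusted p = 1.82e-05), Akr1b7 is a member as well, and Cyp17a1, an androgen synthesis enzyme, fell by 1.69 ± 0.27 (limma adjusted p = 0.00059). The female-biased list had a mean of 0.64 (limma camera adjusted p = 0.00452, but adjusted p = 0.189 with an estimated correlation). In the list of 15 genes of thyroid hormone clearance and response, 5 rose, and 5 rose and 2 fell when adjusted over the list alone. Ugt2b1, Abcc3, Me1 and the organic anion transporter Slco1a4 (0.81 ± 0.13, limma adjusted p = 0.000705) were 4 of them. The thyroid list's mean was 0.42 and its median 0.00 (limma camera adjusted p = 0.0261, but adjusted p = 0.115 with an estimated correlation).

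Of 17 bile acid genes, 2 rose and 3 fell, or 3 and 4 when adjusted over the list alone (mean 0.10, limma camera adjusted p = 0.953), and vehicle replicate 6, at -0.18, lay below the other vehicle arrays in the list's mean. Fgfr4, the receptor for the ileal signal that restrains bile acid synthesis, fell by 0.47 ± 0.07 (limma adjusted p = 0.000478), and Cyp7a1, the rate-limiting enzyme, stood at 0.74 ± 0.39 (limma adjusted p = 0.254). The repressor Nr0b2 rose by 1.44 ± 0.32 (limma adjusted p = 0.00674), a call that was lost without replicate 2 (1.10, limma adjusted p = 0.0550).

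Several lists of markers of other cell types had lower means at 978.5 mg/kg, with few single members passing, while the means of bile duct and general hepatocyte markers lay near 0 and that of periportal hepatocyte genes at -0.26 (exact permutation p = 0.0119). All 14 macrophage markers had lower means, 1 of them fell over all genes and 3 fell when adjusted over the list alone (list mean -0.55, exact permutation p = 0.0119, limma camera adjusted p = 0.000279, but adjusted p = 0.434 with an estimated correlation). The scavenger receptor Cd163 fell by 0.77 ± 0.21 (limma adjusted p = 0.0209), a call lost without replicate 1 (adjusted p = 0.113). Of 6 red blood cell markers 3 fell, and 4 fell when adjusted over the list alone (mean -0.82, limma camera adjusted p = 0.00149, but adjusted p = 0.217 with an estimated correlation). Hba-a3, an alpha globin, fell by 1.45 ± 0.32 and Hbb, the beta globin, by 1.36 ± 0.34 (limma adjusted p = 0.00611 and 0.0155), and vehicle replicate 1 was the lowest of its group in Hbb, at 12.34. Without replicate 3 of this dose the limma adjusted p was 0.0571 for Hba-a3 and 0.105 for Hbb, and without replicate 1 it was 0.0538 for Hbb. Means were -0.29 for 15 lymphocyte markers, -0.33 for 16 stellate and fibroblast markers and -0.24 for 12 endothelial markers (limma camera adjusted p = 0.000371, 0.0126 and 0.0261, but adjusted p = 0.26, 0.325 and 0.595 with an estimated correlation). Falls numbered 1, 2 and 1 in these lists, and 4, 3 and 2 when adjusted over the list alone, where 1 stellate marker also rose. Without replicate 1 of this dose the stellate and endothelial lists no longer passed in limma camera (adjusted p = 0.122 and 0.278), nor did the endothelial list without vehicle replicate 2 or 4 (adjusted p = 0.0709 and 0.059), and the endothelial mean did not pass by exact permutation (p = 0.167). The 8 bile duct markers had a mean of -0.03, and 17 hepatocyte markers one of -0.04 (limma camera adjusted p = 0.962 and 0.499), with 1 rise in each over all genes, and 1 and 2 rises and 0 and 3 falls when adjusted over the list alone. At the lower doses the lymphocyte means lay between -0.24 and -0.08 and the stellate means between -0.28 and -0.12. The endothelial means lay between -0.26 and -0.18 there, so they hardly differed by dose. The endothelial list was lowest in replicate 1 of every group, which is 1 of 3 treated but 1 of 6 vehicle arrays.

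At 489.2 mg/kg the largest rises were those of Ces2c, Abcc3 and the clock gene Dbp. Ces2c rose 9.97-fold (3.32 ± 0.26, n = 3 against 6, limma adjusted p = 7.94e-07), Abcc3 9.45-fold (3.24 ± 0.30, limma adjusted p = 4.91e-06) and Dbp 6.39-fold (2.67 ± 0.45, limma adjusted p = 0.00226). Cyp4a8, a fatty acid hydroxylase, rose 4.24-fold (2.08 ± 0.37, limma adjusted p = 0.00339). Slc6a6 fell 6.82-fold (-2.77 ± 0.27, limma adjusted p = 6.9e-06), Angptl4 3.94-fold (-1.98 ± 0.20, limma adjusted p = 9.73e-06) and Npas2 3.47-fold (-1.80 ± 0.17, limma adjusted p = 6.9e-06). In total 412 genes passed in limma, 215 of them higher and 197 lower, and 57 changed at least 2-fold. Without replicate 1 of this dose 157 genes passed, and without replicate 3, 251.

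Of the CAR and PXR targets, 15 of 24 rose, and 16 rose and 2 fell when adjusted over the list alone (mean 0.79, limma camera adjusted p = 2.23e-18, and 0.00343 with an estimated correlation). Alas1 rose by 1.36 ± 0.19 (limma adjusted p = 0.000455). The NRF2 list had 11 rises in 24 genes, and 13 when adjusted over the list alone (mean 0.50, limma camera adjusted p = 2.57e-13, and 0.00755 with an estimated correlation), with Gsta3 at 2.04 ± 0.23 (limma adjusted p = 3.91e-05). Conjugation and export genes gave 10 rises in 28, and 15 when adjusted over the list alone (mean 0.53, limma camera adjusted p = 8.29e-15, and 0.00369 with an estimated correlation). Cyp1a1 had risen 3.43-fold (1.78 ± 0.31, limma adjusted p = 0.0031), 1 of 2 rises beside 1 fall in the aryl hydrocarbon receptor list.

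Of the clock genes, 7 of 17 rose and 3 fell, or 8 and 3 when adjusted over the list alone (mean 0.36, limma camera adjusted p = 0.0238, but adjusted p = 0.128 with an estimated correlation), and the clock axis stood 2.00 above the vehicle. Among genes above the median level of all genes the clock list's mean was -0.08, and with the clock axis as a covariate 19 genes passed over all, with a median limma SE of 0.25 in place of 0.12 and a median size of the difference of 0.54 in place of 0.53 over the 412 genes. PPARA targets tended downward at this dose, with 5 falls and 1 rise over all genes and 12 falls and 1 rise when adjusted over the list alone (mean -0.24, limma camera adjusted p = 2.4e-05, but adjusted p = 0.339 with an estimated correlation). Plin2 fell by 1.18 ± 0.14 (limma adjusted p = 4.63e-05), and Cyp4a1 stood at -0.91 ± 0.26 (limma adjusted p = 0.069). The PPARA call was lost without replicate 3 of this dose (mean -0.12, limma camera adjusted p = 0.143). Cholesterol genes had a mean of 0.42 and 9 rises when adjusted over the list alone, but no single member passed over all genes in limma (limma camera adjusted p = 4.67e-06, but adjusted p = 0.353 with an estimated correlation). The macrophage list lay at -0.35 (limma camera adjusted p = 0.0012, but adjusted p = 0.497 with an estimated correlation) and at 0.10 without replicate 1 of this dose, where it no longer passed.

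At 244.6 mg/kg genes of cell division were higher than in the vehicle, beside rises of Abcc3, Ces2c and Gsta3. Ect2, needed for cytokinesis, rose 7.72-fold (2.95 ± 0.76, n = 3 against 6, limma adjusted p = 0.0368), cyclin A2, Ccna2, 7.37-fold (2.88 ± 0.64, limma adjusted p = 0.0147) and the mitotic kinase Cdk1 7.18-fold (2.84 ± 0.60, limma adjusted p = 0.00983). The proliferation marker Mki67 rose 6.93-fold (2.79 ± 0.61, limma adjusted p = 0.0122). Of 31 cell cycle genes all had higher means, 23 rose over all genes and 28 rose when adjusted over the list alone. The list's mean was 1.47 (SD 0.389 between treated arrays, exact permutation p = 0.0119, limma camera adjusted p = 5.05e-34, and 0.0466 with an estimated correlation). Without replicate 1 of this dose the limma adjusted p of Mki67 was 0.124, of Cdk1 0.102, of Ccna2 0.137 and of Ect2 0.221, and without replicate 2 they were 0.0624, 0.0661, 0.0858 and 0.134. The call of Ect2 was also lost without vehicle replicates 1, 2, 3 or 4 or replicate 3 of this dose, the limma adjusted p running from 0.0531 to 0.0747.

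At the other doses the means of the cell cycle genes were 0.28, 0.30, -0.22 and 0.38 at 61.2, 122.5, 489.2 and 978.5 mg/kg, with no member passing at the first 3 of these and Mcm4 alone at 978.5 mg/kg (0.71 ± 0.21, 2 of 3 arrays above all vehicle arrays, limma adjusted p = 0.0336), a call lost without replicate 1 (adjusted p = 0.275) or replicate 3 (adjusted p = 0.122) of that dose and without vehicle replicate 2, 3 or 4 (adjusted p = 0.0617, 0.0585 and 0.0596). Camera passed the list at 61.2, 122.5 and 978.5 mg/kg (limma camera adjusted p = 0.00154, 0.00132 and 0.00126, but adjusted p = 0.545, 0.615 and 0.595 with an estimated correlation). These calls were lost without replicate 1 at 61.2 mg/kg (mean -0.04), replicate 3 at 122.5 mg/kg (0.05) and replicate 1 at 978.5 mg/kg (0.17). A direct contrast of 244.6 with 489.2 mg/kg, chosen after these genes were seen, called 242 genes in limma, 213 higher and 29 lower at 244.6 mg/kg, among them 22 of the 31 cell cycle genes. Mki67 was higher by 3.48 ± 0.70 in that contrast (limma adjusted p = 0.0112, n = 3 against 3). The list itself was higher by a mean of 1.69 (limma camera adjusted p = 3.1e-38, but adjusted p = 0.125 with an estimated correlation). Differences of 244.6 mg/kg from the remaining doses were not tested. The contrast's count fell to 41 without replicate 1 and 59 without replicate 2 at 244.6 mg/kg, and to 69 and 117 without replicates 1 and 3 at 489.2 mg/kg.

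Genes for handling foreign compounds had risen at 244.6 mg/kg as well. Abcc3 rose 7.40-fold (2.89 ± 0.30, limma adjusted p = 1.66e-05), Ces2c 6.86-fold (2.78 ± 0.26, limma adjusted p = 4.19e-06), Gsta3 6.41-fold (2.68 ± 0.23, limma adjusted p = 3.04e-06) and Akr7a3 4.07-fold (2.02 ± 0.26, limma adjusted p = 0.000187). The NRF2 list had 14 rises in 24 genes, and 19 when adjusted over the list alone (mean 0.69, limma camera adjusted p = 2.43e-25, and 0.000435 with an estimated correlation). CAR and PXR targets gave 10 rises in 24, and 15 rises and 1 fall when adjusted over the list alone (mean 0.66, limma camera adjusted p = 3.08e-16, and 0.00251 with an estimated correlation). Conjugation and export genes gave 14 rises in 28, and 21 rises and 1 fall when adjusted over the list alone (mean 0.63, limma camera adjusted p = 3.65e-24, and 0.000435 with an estimated correlation). Psat1 rose by 1.77 ± 0.29 (limma adjusted p = 0.00162) and Me1 by 1.51 ± 0.19 (limma adjusted p = 0.00017). Slc6a6 fell 5.52-fold (-2.46 ± 0.27, limma adjusted p = 3.29e-05) and Oat, the ornithine aminotransferase of pericentral hepatocytes, by 1.42 ± 0.23 (limma adjusted p = 0.0015). In total 420 genes passed in limma, 359 higher and 61 lower, and 102 changed at least 2-fold, 96 upward. Without replicate 1 of this dose 112 genes passed, without replicate 2, 230, and with the clock axis as a covariate 263, 190 of them higher and 73 lower. Macrophage markers had a mean of -0.41 and lymphocyte markers one of -0.24 (limma camera adjusted p = 0.000175 and 0.000225, but adjusted p = 0.44 and 0.272 with an estimated correlation). Replicate 1 of this dose was the lowest in both lists, at -0.78 and -0.44. Replicates 2 and 3 stood at -0.32 and -0.14 for macrophage markers and at -0.13 and -0.14 for lymphocyte markers.

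At 122.5 mg/kg the largest rises that passed were those of Ces2c, Gsta3 and Abcc3. Ces2c rose 4.55-fold (2.19 ± 0.26, n = 3 against 6), Cyp3a23-3a1 1.97-fold (0.98 ± 0.12) and Ugt2b1 1.96-fold (0.97 ± 0.11), each with a limma adjusted p of 0.000292, and Gsta3 rose 3.24-fold (1.70 ± 0.23, limma adjusted p = 0.00165). In total 16 genes passed in limma, all of them higher, and 862 had an unadjusted p under 0.05. With array weights 357 genes passed, 212 higher and 145 lower, with an unadjusted p and a 1.5-fold change 31 were higher and 40 lower, with the replicate block 4 passed, and with the clock axis as a covariate 4. Abcc3 (1.62 ± 0.30, limma adjusted p = 0.0323) and Akr7a3 (1.48 ± 0.26, limma adjusted p = 0.0267) were among the 16, as was the microsomal epoxide hydrolase Ephx1 (0.74 ± 0.11, limma adjusted p = 0.00639). Without replicate 3 of this dose Abcc3 (limma adjusted p = 0.429), Akr7a3 (adjusted p = 0.401) and Ephx1 (adjusted p = 0.135) did not pass and 4 genes did. Without replicate 2 their limma adjusted p-values were 0.169, 0.169 and 0.0574, and 6 genes passed. Abcc3 was also lost without replicate 1 of this dose (limma adjusted p = 0.0581) or replicate 3 at 244.6 mg/kg (adjusted p = 0.0525). Leaving out vehicle replicate 1, 2, 3, 5 or 6 gave 10, 8, 7, 7 and 7 genes, with limma adjusted p-values up to 0.0811 for Abcc3 and 0.0582 for Akr7a3, neither of which passed in any of these runs. Of the CAR and PXR targets 7 of 24 rose, and 10 when adjusted over the list alone (mean 0.45, limma camera adjusted p = 5.21e-16, and 0.00368 with an estimated correlation). Conjugation and export genes gave 5 rises in 28, and 16 when adjusted over the list alone (mean 0.41, limma camera adjusted p = 1.21e-21, and 0.000968 with an estimated correlation), and NRF2 targets 5 in 24, and 9 when adjusted over the list alone (mean 0.37, limma camera adjusted p = 1.03e-14, and 0.0048 with an estimated correlation). Slc6a6 stood at -1.37 ± 0.27 (limma adjusted p = 0.0501).

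At 61.2 mg/kg, the lowest dose, 2 genes passed in limma. Gsta3 rose 2.76-fold (1.47 ± 0.23, n = 3 against 6, limma adjusted p = 0.0255) and Ugt2b1 1.79-fold (0.84 ± 0.11, limma adjusted p = 0.00572). An unadjusted p under 0.05 was reached by 779 genes. With any of the 3 arrays of this dose left out neither gene passed in limma, the adjusted p of Ugt2b1 running from 0.0691 to 0.0966, and Gsta3 was also lost without vehicle replicate 1, 2, 3 or 6, which left 1 gene. Ces2c, at 1.24 ± 0.26 (limma adjusted p = 0.196), and Akr7a3, at 1.10 ± 0.26 (limma adjusted p = 0.365), did not pass although all 3 arrays lay above the vehicle. More genes passed within the lists than over all genes. CAR and PXR targets had a mean of 0.31, with 1 rise over all genes and 10 when adjusted over the list alone (limma camera adjusted p = 3.72e-10, and 0.0196 with an estimated correlation). NRF2 targets had a mean of 0.33 and 1 rise, and 11 when adjusted over the list alone (limma camera adjusted p = 6.75e-14, and 0.00884 with an estimated correlation). For conjugation and export the mean was 0.29 with 2 rises, and 9 when adjusted over the list alone (limma camera adjusted p = 3.5e-14, and 0.0082 with an estimated correlation). These 3 lists alone passed with an estimated correlation at all 5 doses, but they share genes and are not separate lines of evidence. Their rises over all genes at this dose were those of Ugt2b1 and Gsta3, each counted in 2 lists. In each of these 3 lists, and in the thyroid and esterase lists, the mean of every treated array lay above all vehicle arrays at all 5 doses (exact permutation p = 0.0119). The esterase mean rested largely on Ces2c at every dose, and the thyroid mean at 978.5 mg/kg on Abcc3, Ugt2b1 and Me1. Neither mean shows a rise of most members.

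**Figure D1:**
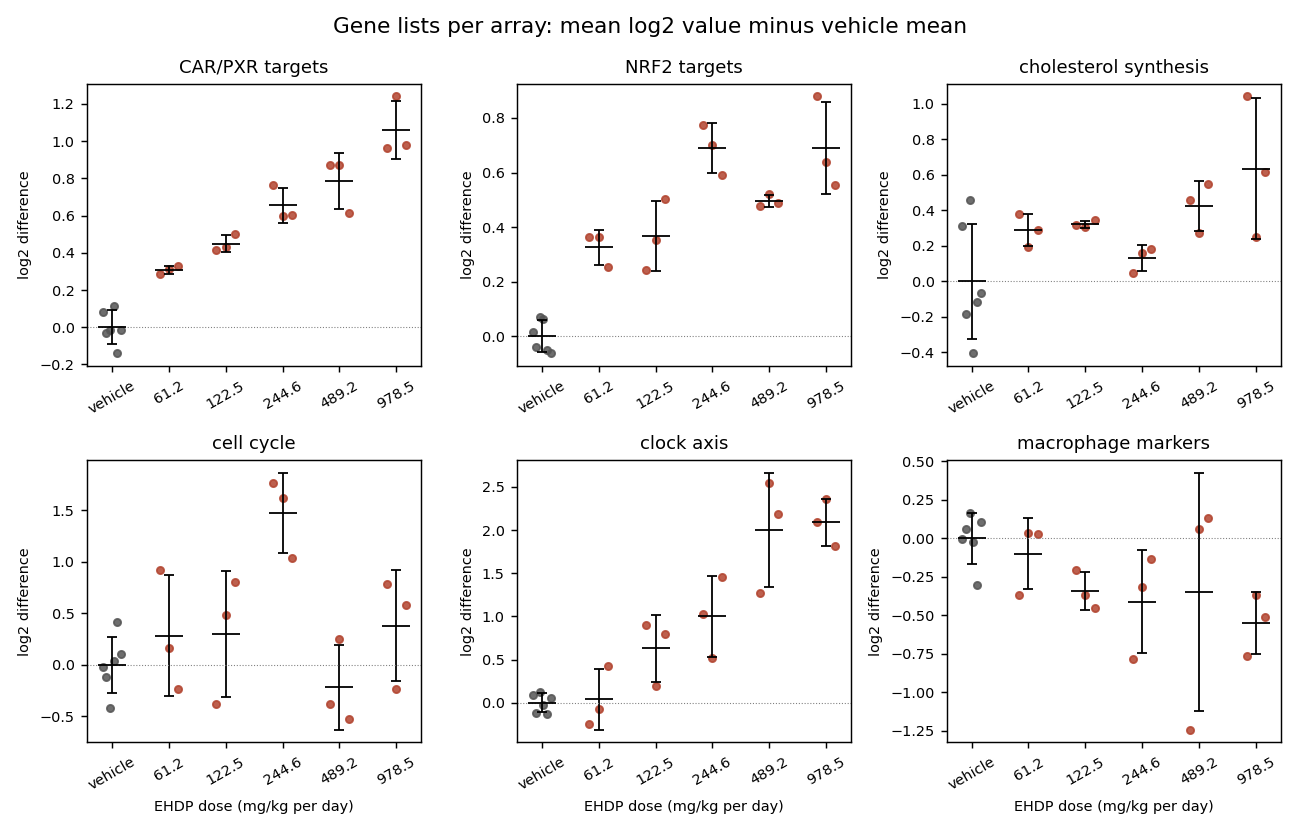
Mean log2 expression of 6 gene lists on each array minus the vehicle mean (points), by dose in mg/kg, with a bar for the mean of each group. CAR and PXR targets reached 1.06 at 978.5 mg/kg, cell cycle genes stood at 1.47 at 244.6 mg/kg and at -0.22 at 489.2 mg/kg, and the clock axis lay at 2.00 and 2.09 at the highest doses.

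Between the highest doses, 978.5 against 489.2 mg/kg, 15 genes differed in limma, all higher at 978.5 mg/kg. Sult2a2 was higher by at least 3.29 ± 0.30 (n = 3 against 3, limma adjusted p = 1.68e-05), a lower bound since its level at 489.2 mg/kg, 4.18, was close to the lowest signals, and Ttc39a, a tetratricopeptide repeat protein, by 1.41 ± 0.17 (limma adjusted p = 0.000375). Abcb1a was higher by 1.13 ± 0.20 (limma adjusted p = 0.0392) and Gadd45b by 1.18 ± 0.22 (limma adjusted p = 0.0442). Ces2c (0.47 ± 0.30, limma adjusted p = 0.502) and Abcc3 (0.26 ± 0.34, limma adjusted p = 0.78) did not pass. Camera placed CAR and PXR targets higher at the top dose (limma camera adjusted p = 1.06e-05, but adjusted p = 0.29 with an estimated correlation). With only the arrays of these groups limma called 0 genes, where 1940 had an unadjusted p under 0.05 in the fit of all arrays, and the count was 3 with a second quantile normalisation, 6 with array weights and 42 with the mean of probe sets. It was 2 without replicate 3 and 126 without replicate 2 at 978.5 mg/kg, 8, 44 and 3 without replicates 1, 2 and 3 at 489.2 mg/kg, and 34 without vehicle replicate 6. Leaving out vehicle replicate 1 or 2 gave 8 and 6, replicate 1 or 2 at 61.2 mg/kg 7 and 6, replicate 2 or 3 at 122.5 mg/kg 9 and 6, and replicate 1 at 244.6 mg/kg 7.

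Over the whole series of doses 1589 genes had a trend with dose rank in limma, 861 upward and 728 downward. Slc6a6 fell by 0.75 ± 0.046 log2 units per dose step (limma adjusted p = 3.92e-10). Ces2c rose by 0.77 ± 0.050 per step (limma adjusted p = 7.98e-10) and Abcc3 by 0.77 ± 0.055 (limma adjusted p = 5.29e-09). Pir (0.28 ± 0.022, limma adjusted p = 2.21e-08) and Htatip2, a short-chain reductase (0.20 ± 0.019, limma adjusted p = 8.18e-07), rose with little scatter, although vehicle replicate 6 lay below the other vehicle arrays in Htatip2, at 8.68. A test for any difference over the 5 doses called 799 genes. Of the genes called at 978.5 mg/kg, 590 of those that rose and 438 of those that fell passed at no lower dose, and 2 and 14 of the risen genes first passed at 61.2 and 122.5 mg/kg.

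**Figure D2:**
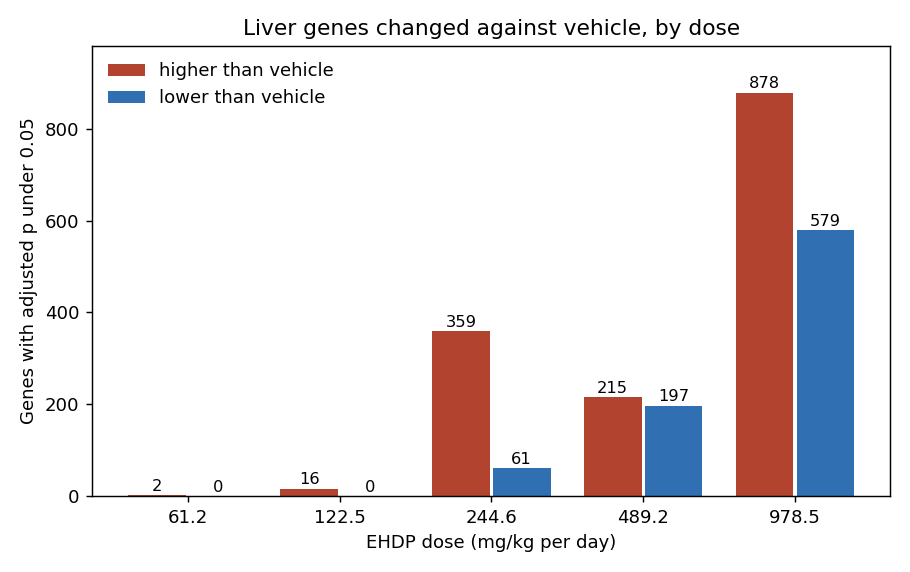
Number of genes that rose and fell against the vehicle in limma, as bars side by side, by dose in mg/kg. The bars run from 2 rises at 61.2 mg/kg to 878 rises and 579 falls at 978.5 mg/kg.

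Calls of neighbouring doses overlapped. Shared between 978.5 and 489.2 mg/kg were 172 risen and 118 fallen genes, Ces2c, Slc6a6 and Npas2 among them, and no gene was called in opposite directions. Independent lists of these sizes would share 13.3 and 8.02. The doses share their vehicle arrays, so the correlation of the log2 differences across genes, 0.665, stands beside 0.320 for simulated unchanged groups, and the covariance, 0.0401, beside 0.00615. With separate vehicle arrays for each dose the correlation was 0.505, the covariance 0.0336, and the shared genes numbered 73 to 115 upward and 37 to 66 downward over 20 assignments. Without replicate 1 at 489.2 mg/kg the doses shared 134 genes in place of 290. Between 978.5 and 244.6 mg/kg 182 risen and 46 fallen genes were shared, against 22.2 and 2.48 for independent lists, with a covariance of 0.0431 against a simulated 0.00578 and 0.0366 with separate vehicle arrays. Between 489.2 and 244.6 mg/kg the shared genes were 66 and 23, against 5.43 and 0.845, and the correlation, 0.409, lay closer to the simulated 0.333 and was 0.258 with separate vehicle arrays (covariance 0.0213, simulated 0.00639, separate 0.0148). The 16 genes risen at 122.5 mg/kg had all risen at 244.6 mg/kg, against 0.404 for independent lists, and separate vehicle arrays left 4 to 13 of them shared.

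Benchmark doses, at which a gene's fitted curve left the vehicle level by 1 residual SD, were lowest for Ugt2b1 and Gsta3 among the named genes. For Ugt2b1 the value was 12.1 mg/kg (95% interval 6.65 to 18.3), for Gsta3 15.1 mg/kg, for Pir 17.5 mg/kg, for Cyp3a23-3a1 18.4 mg/kg (9.41 to 36.4) and for Ces2c 20.2 mg/kg (11.3 to 37.6). These lie below 61.2 mg/kg, the lowest dose given, and rest on interpolation from the vehicle. Slc6a6 left at 56.8 mg/kg (21.6 to 94.0), Npas2 at 92.9 mg/kg (38.3 to 158.9) and Cyp1a1 at 234.2 mg/kg. Over 414 genes with a trend and at least a 1.5-fold change the median was 109.6 mg/kg (quartiles 57.0 and 188.3, jackknife SE over arrays 25.2), and 117 of them had a value below the lowest dose. The median was 25.6 mg/kg for 12 NRF2 targets, 36.4 mg/kg for 12 conjugation and export genes, 39.9 mg/kg for 15 CAR and PXR targets, 108.3 mg/kg for 11 clock genes and 157.8 mg/kg for 10 cholesterol genes. With a change of 0.5 residual SD the median over all genes was 50.4 mg/kg, and with 1.5 it was 208.1 mg/kg.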

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

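The tests of cell cycle genes, of clock genes and of other cell types, fits with the clock axis as a covariate and the contrast of 244.6 with 489.2 mg/kg were chosen only after results were seen. Among 131 measures of the vehicle arrays, 10 had an array set apart from its group, where chance marks about 1 in 20, or 6.55. Vehicle replicate 6 accounts for 6 of the 10. Its mean correlation with the other arrays was 0.988, its list means were 0.0845 for the aryl hydrocarbon receptor, -0.18 for bile acids and 0.63 for neutrophil markers, and it stood at 6.74 in Gadd45b and 8.68 in Htatip2. The others were replicate 3 in bile duct markers at -0.21, replicate 4 in Akr7a3 at 11.81, replicate 2 in Per3 at 4.83 and replicate 1 in Hbb at 12.34. Beyond the named genes, 325 probe sets without a single gene symbol changed at 978.5 mg/kg.

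Chance splits of the 9 arrays of a dose set the counts in context, and the real split is counted among the 84. At 61.2 mg/kg 5 of 84 splits called at least the real 2 genes, the highest other 107, so a split by chance was not excluded there. At 122.5 mg/kg 3 splits reached the real 16 and the highest other called 83. Splits that call several times the real count, such as those that join vehicle replicates 5 and 6 with a treated array, point to a structure of the samples beside dose. At 244.6, 489.2 and 978.5 mg/kg only the real split, 1 of 84, reached 420, 412 and 1457 genes, with 32, 211 and 54 as the highest others.

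For gene lists called by camera, the splits that reached the real count, the real split included, were 2 of 84 at 61.2 mg/kg (real 15, highest other 15) and 3 at 489.2 mg/kg (real 16, highest other 16). They were 13 at 122.5 mg/kg (real 10, highest other 15), 19 at 244.6 mg/kg (real 9, highest other 14) and 8 at 978.5 mg/kg (real 12, highest other 14), where a split by chance was not excluded for the number of lists. Of 100 orders of the 21 arrays, the real order included, only the real order reached 1589 trend genes (highest other 19) and 799 genes of the F test (highest other 2). For 978.5 against 489.2 mg/kg only the real split, 1 of 10, reached 15 genes (highest other 12), and for 244.6 against 489.2 mg/kg only the real split, 1 of 10, reached 242 (highest other 2), too few splits for either contrast.

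Cell cycle genes stood higher at 244.6 mg/kg, by a list mean of 1.47. A single array could carry such a difference, but the lowest mean with 1 array of that dose left out was 1.32. With the clock axis as a covariate the mean was 1.87 (limma camera adjusted p = 1.85e-34). Dividing immune cells might also raise it and stay an open explanation, since the higher of the lymphocyte and macrophage list means, -0.24, does not measure a small dividing subset. No test explains why the genes were not higher at 489.2 mg/kg.

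Clock genes shifted with dose, by 2.09 on the clock axis at 978.5 mg/kg. The hour of collection may differ between groups, and 0 of the 21 arrays carry an hour of collection in their labels, so that explanation stays open. A single array could also carry the shift, but the lowest difference with 1 of the 9 arrays left out was 1.95. That value describes how the axis lies over the arrays. It does not test the shift, since the axis was built after the shifts of its genes had been seen.

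Several lists of markers of other cell types had lower means at 978.5 mg/kg, with a macrophage list mean of -0.55. Dilution of every other cell type alike could lower them. The gap between macrophage and bile duct lists was -0.52 (exact permutation p = 0.0238, not adjusted, and at most that with any 1 bile duct marker left out). These lists were paired after their means, -0.55 and -0.03, had been seen, so the test cannot exclude dilution. Less blood in the sample might lower red blood cell markers and stays open, since the lower macrophage list (exact permutation p = 0.0119) is part of the pattern itself. Without vehicle replicate 6 the macrophage mean was -0.53.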

How the results depend on the processing

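Fits without arrays in doubt, with the clock axis as a covariate and for 244.6 against 489.2 mg/kg, and all alternatives for the genes shared between doses, were tests chosen only after results were seen, and the other settings were chosen before the data were examined. With 3 arrays per dose the counts depend strongly on single arrays, and those at 61.2 and 122.5 mg/kg and between the highest doses are the least stable. The main counts were 2, 16, 420, 412 and 1457 genes from the lowest dose to the highest, 15 between the highest doses and 1589 for the trend.

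The mean of a gene's probe sets gave 42 genes between the highest doses (37 higher, 5 lower). Among genes above the median level 250 passed at 244.6 mg/kg (200 higher, 50 lower) and 26 between the highest doses. The eBayes trend and robust options gave 1 gene at 61.2 mg/kg and 27 between the highest doses. Array weights gave 357 genes at 122.5 mg/kg (212 higher, 145 lower), 766 at 244.6 mg/kg (590 higher, 176 lower) and 6 between the highest doses. Median centring gave 27 between the highest doses, and a second quantile normalisation gave 3 there and 1 at 61.2 mg/kg. The floor at the 20th percentile left 1 gene at 61.2 mg/kg.

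With adjusted p and 1.5-fold, 209, 173 and 361 genes passed at 244.6, 489.2 and 978.5 mg/kg and 332 for the trend. With unadjusted p and 1.5-fold, 42, 71 and 446 passed at 61.2, 122.5 and 978.5 mg/kg, 368 for the trend and 174 between the highest doses. With only the arrays of the compared groups, 1, 8, 160 and 961 passed at 61.2, 122.5, 489.2 and 978.5 mg/kg, and limma called 0 between the highest doses, where 1940 had an unadjusted p under 0.05 in the fit of all arrays. Treated arrays alone on log2 dose gave 441 trend genes, and the F test 799.

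With the replicate number as a block (replicate block) 1 gene passed at 61.2 mg/kg and 4 at 122.5 mg/kg. Vehicle replicates 4, 5 and 6 share their number with no treated array, so in that fit each dose is compared with vehicle replicates 1, 2 and 3 alone. Calls lost with the block can therefore come from fewer vehicle arrays as well as from the block itself. The arrays were not treated as paired, since only 17 of 45 pairs of arrays with the same number had residuals that correlated above 0.1 (lowest -0.23). The mean was 0.0365, against -0.0181 for different numbers (exact permutation p = 0.0696 over 7776 ways of numbering). As a hint from the data, 10 of 18 arrays correlated best with their own number, where 6 would by chance (exact permutation p = 0.127), and the endothelial list mean was lowest in replicate 1 of all 6 groups (-0.60 to -0.37, with every other array at -0.21 or above), so a link between arrays of the same number was not excluded.

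Without vehicle replicate 6 and replicate 3 of 978.5 mg/kg 758 genes passed at that dose, and without vehicle replicate 6 and replicate 1 of 489.2 mg/kg 183 did. With the clock axis as a covariate 4, 263, 19 and 116 genes passed at 122.5, 244.6, 489.2 and 978.5 mg/kg (4 and 0, 190 and 73, 7 and 12, 41 and 75 higher and lower). Over the genes called without it, the median size of the difference at those doses was 0.89, 0.58, 0.53 and 0.43 without the axis and 0.82, 0.62, 0.54 and 0.49 with it, and the median limma SE 0.11, 0.12, 0.12 and 0.10 without and 0.13, 0.17, 0.25 and 0.23 with it. Errors grew with the axis, as a share of 0.88 of its variance lay between dose groups. Differences fitted with it are poorly determined, so whether those of single genes shrank cannot be told. Camera with an estimated correlation kept 3 of 12 lists at 978.5 mg/kg. The median benchmark dose was 50.4 mg/kg at 0.5 residual SD and 208.1 mg/kg at 1.5.

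With 1 array left out the counts ranged from 0 to 3 at 61.2 mg/kg, 4 to 18 at 122.5 mg/kg, 112 to 453 at 244.6 mg/kg, 157 to 514 at 489.2 mg/kg and 702 to 1594 at 978.5 mg/kg. They ranged from 1088 to 1730 for the trend, 2 to 126 between the highest doses, 41 to 339 for 244.6 against 489.2 mg/kg, 134 to 338 for shared genes, 9 to 14 for lists and 94.5 to 120.8 mg/kg for the median benchmark dose.

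Signs reversed in 6 list results, and the causes were not tested. Those of the clock list follow in part from the settings. The clock axis holds members of that list, so as a covariate it takes up their shift. Among genes above the median level, only the list's members above that level are averaged. At 489.2 mg/kg the clock list was -0.0826 among genes above the median level and -0.00211 with the clock axis as a covariate, and the acute phase list was -0.13 with that covariate. With 1 array left out, the acute phase list at 489.2 mg/kg ranged from -0.0249 (without replicate 3) to 0.37, the macrophage list at 489.2 mg/kg from -0.59 to 0.10 (without replicate 1) and the cell cycle list at 61.2 mg/kg from -0.0362 (without replicate 1) to 0.54.

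Of the results of named genes, 5 went weaker and 1 stronger with median centring, 11 and 1 with the mean of probe sets and 49 and 5 with the block. Of list results, 45 went weaker with an estimated correlation, 35 weaker and 7 stronger with fry, 5 weaker with the mean of probe sets, 15 weaker and 1 stronger among genes above the median level, 13 weaker and 1 stronger with the block and 12 weaker with the clock axis. Of 213 gene calls 82 were lost without some array, and of 62 list calls 27.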

Other observations

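The clock axis, the contrast of 244.6 with 489.2 mg/kg and the other tests of the cell cycle pattern were chosen only after results were seen, whereas the comparisons with vehicle and the gene lists were fixed before. Genes of hepatocyte zones fell in part. At 978.5 mg/kg the periportal list of 15 had 1 rise and 4 falls, or 2 and 6 when adjusted over the list alone (mean -0.26, limma camera adjusted p = 0.0561). The histidine ammonia-lyase Hal fell by 0.63 ± 0.14 and the urea cycle enzyme Asl by 0.38 ± 0.08 (limma adjusted p = 0.00684 and 0.00561, n = 3 against 6). In the pericentral list of 11, 2 fell at 244.6, 489.2 and 978.5 mg/kg, or 3, 2 and 2 when adjusted over the list alone, and Oat was 1 of them each time. The pericentral list passed in camera at 61.2, 244.6 and 489.2 mg/kg (limma camera adjusted p = 0.0402, 0.00456 and 0.0362, but adjusted p = 0.288, 0.164 and 0.339 with an estimated correlation). The call at 61.2 mg/kg was lost without vehicle replicate 5 or 6 or replicate 1 or 2 of that dose, and the call at 489.2 mg/kg without vehicle replicate 5 or 6 or replicate 2 or 3 of that dose.

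Outside the lists, Slc22a8, a renal-type organic anion transporter, fell by 1.74 ± 0.20 at 978.5 mg/kg (limma adjusted p = 1.7e-05), as did the phosphate transporter Slc34a2 (-1.64 ± 0.20, limma adjusted p = 3.25e-05). Cidea, which enlarges lipid droplets, rose by 2.15 ± 0.40 (limma adjusted p = 0.00176). The neuronal regeneration related protein Nrep fell by 1.75 ± 0.30 (limma adjusted p = 0.00104).

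Other lists moved little at 978.5 mg/kg, while the acute phase list passed in camera at 489.2 mg/kg. Its mean was 0.19 at 489.2 mg/kg. Without replicate 3 of that dose the mean was -0.0249 and the list no longer passed (limma camera adjusted p = 0.893). Acute phase genes (28) had 1 rise and 1 fall at 978.5 mg/kg (limma camera adjusted p = 0.633), with 0 of either when adjusted over the list alone. Sugar metabolism genes (20) had 3 falls there, the same when adjusted over the list alone (mean -0.18, limma camera adjusted p = 0.0742). Glucocorticoid targets (14) had 1 rise, of the growth inhibitor Ddit4 (1.74 ± 0.35, limma adjusted p = 0.00292), and 2 falls, the same when adjusted over the list alone (limma camera adjusted p = 0.499). Antigen presentation genes (23) had 1 rise and 1 fall (limma camera adjusted p = 0.739). No neutrophil marker of 7 passed in limma (mean -0.25, limma camera adjusted p = 0.499), with vehicle replicate 6 set apart. Pancreas markers (11) had 1 fall (mean -0.15, limma camera adjusted p = 0.093) and housekeeping genes (9) 1 rise, of Hprt1, a purine salvage enzyme (0.57 ± 0.08, limma adjusted p = 0.000213, list mean 0.08, limma camera adjusted p = 0.406).

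Rises of cell cycle genes at 244.6 mg/kg, by 1.47, could reflect a brief wave of hepatocyte division. Counts of Mki67-stained hepatocyte nuclei on day 2 to day 5 at that dose and at 489.2 mg/kg would test it.

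The shift of 2.09 on the clock axis may come from the hour of collection or from feeding. Livers taken at fixed hours through a day, with food intake recorded, would separate these, with the phase of Dbp and Npas2 as the readout.

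Sult2a2, higher by at least 3.29 between the highest doses while Ces2c did not pass in that contrast, could answer to another receptor than Ces2c. A difference between dose responses was not tested here, and the count for this contrast ran from 2 to 126 with 1 array left out. Rats without CAR or without PXR given 978.5 mg/kg would test it.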
